A study of Rattus norvegicus with 4 samples.

How the data were processed

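The samples were cartilage of 4 male Sprague Dawley rat samples, 2 labelled healthy and 2 labelled osteoarthritis. Per the labels' protocols, total RNA was isolated with TRIzol, purified with RNeasy columns, and polyA RNA libraries were made with standard Illumina protocols. The submitters' processing notes name fastp, a read trimmer, and TopHat, a spliced aligner, without versions, and the genome build hg38, which is a human build, while the gene symbols in the deposited tables are rat symbols. The counting tool, the annotation and the build behind the counts are not given in the sources used here, nor is strandedness, so reads of overlapping genes cannot be told apart. The authors deposited a table of raw read counts per gene and a table of FPKM values for the same genes and libraries. Each of the 67506 FPKM values above 0 equalled the deposited count divided by a gene length and the column total to within a relative difference of 1e-08, so the FPKM table is no independent measurement, and the gene length it implies was used where length is named. Of the 24005 symbols, 17871 matched a symbol and 2138 a synonym in the RefSeq table of assembly GRCr8, and 3996 matched neither. That table was used for names only.

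Samples were grouped by the labels on disease state. The treatment label divides the samples in the same way, and no batch or pairing is labelled. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The adjustment over a list alone, used in the results, was not part of that plan. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 15282, library sizes were scaled by TMM, and the quasi-likelihood F test compared osteoarthritis with control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The TMM factors were 1.01 and 0.923 for the control and 1.21 and 0.891 for the osteoarthritis libraries. The common dispersion was 0.391 and the prior degrees of freedom 3.34. CPM values use TMM-scaled library sizes, and standard errors of log2 fold changes were taken as the fold change divided by the root of the F statistic. With 2 samples against 2, an exact permutation test of a single value cannot go below p = 0.333, so none is given.

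The 41 lists, 24 programmes and 17 cell types, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over all lists. A list needed at least 5 tested members. Named genes were to be the 8 highest and 8 lowest by fold change among those past the threshold, with a mean of at least 5 CPM in the higher group, the libraries of the groups apart, and a symbol of their own. As no gene passed, the fallback of that rule took the 8 of each direction with the smallest unadjusted p, and the conditions on expression, separation and symbol were kept. The rule also names up to 4 members per list with the smallest unadjusted p and 14 genes fixed by name, of which 1 is not reported here. DESeq2 1.42.0 was run as an alternative, as were limma-voom, edgeR's likelihood ratio test, other scalings and filters, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, and fits without each library. In the latter, the lone sample of a group is assumed to vary like the other group.

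The scripts were tested on simulated data for the comparison of osteoarthritis with control, with the means, library sizes and dispersions of the 15282 genes, 200 changed genes and 1 changed list. At the estimated dispersions, edgeR recovered 65 of 100 genes changed 16-fold and 6 of 100 changed 4-fold, with 5 false calls, and DESeq2 recovered 85 and 42, with 121 false calls. At a dispersion of 0.1, edgeR recovered 100 and 72. These shares need not hold for the real data. There edgeR's quasi-likelihood test called 0 genes, though Pla2g2a had a fitted change of 33.2-fold (adjusted p = 0.0824). The 0 calls therefore do not show that such changes were absent. Camera called the 1 changed list and 0 of 40 unchanged lists. Genes were drawn independently there, so this cannot show how often camera calls unchanged lists whose members are correlated. In the real data the estimated correlation was as high as 0.953, in the megakaryocyte and platelet list. Depth was 24492412 to 28270779 counts per library, and the labels used here name no molecular identifiers, so intervals cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.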

Results

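Messenger RNA was sequenced from joint cartilage of male Sprague Dawley rats, an outbred laboratory strain, aged 8 to 12 weeks and weighing 140 to 230 g. The labels put 2 libraries in a healthy control group and 2 in an osteoarthritis group. All 4 are labelled rat, but the design text speaks of normal mice beside osteoarthritis rats. If the controls were mice, the fold changes would also hold a species difference, which was not tested. By the series' title and design text, osteoarthritis was induced with monosodium iodoacetate, an inhibitor of glycolysis that damages cartilage when injected into a joint, and the study was about Xiaogu San, a herbal preparation. Both osteoarthritis libraries carry the treatment label of that preparation and no library is labelled as untreated osteoarthritis, so the comparison below is of control cartilage against cartilage with both labels, and the 2 labels cannot be separated. Nothing in the labels says that the libraries came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may be technical. The totals were 28156020 and 28270779 counts in the control libraries and 24492412 and 25994449 in the osteoarthritis libraries. At least 1 count was found for 14770 and 15739 genes in the control libraries and for 19272 and 17725 genes in the osteoarthritis libraries. Across the 15282 genes tested, Pearson's r of log2 CPM was 0.861 between the control libraries and 0.869 between the osteoarthritis libraries, and 0.764 to 0.785 for the 4 pairs from different groups. Spearman's correlation was 0.934 between the control libraries, 0.89 between the osteoarthritis libraries and 0.813 to 0.84 for the pairs from different groups. These correlations are across genes, which are not independent replicates.

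Genes at low counts were fewer in the control libraries: 126 and 190 genes had 1 count there, against 977 and 1219 in the osteoarthritis libraries.

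**Figure D1:**
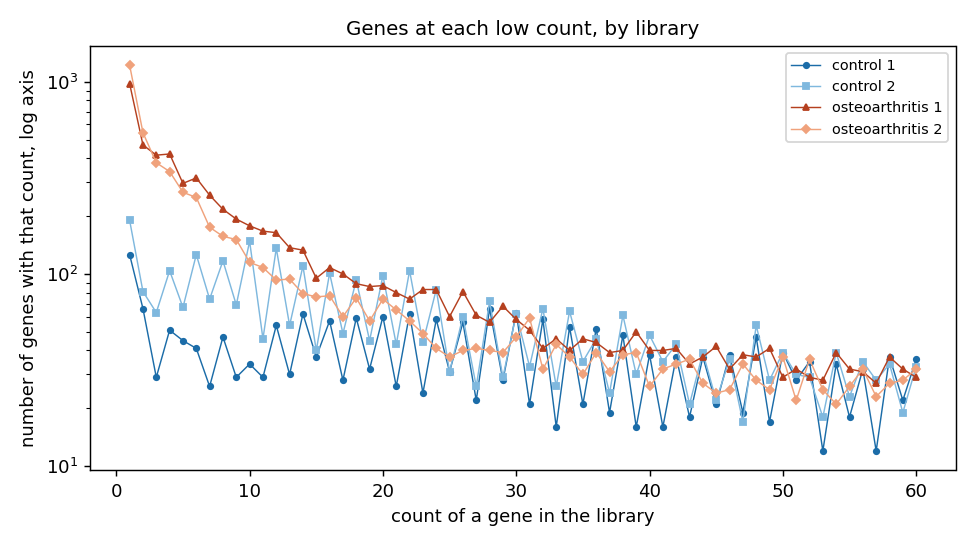
Number of genes at each count from 1 to 60, on a log axis, in each library. The control libraries have 126 and 190 genes with 1 count against 977 and 1219 in the osteoarthritis libraries, and their curves alternate between even and odd counts.

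The comparison asked how the transcripts of cartilage differed between healthy rats and rats labelled osteoarthritis. At a preset inter-gene correlation, the lists of cartilage matrix, bone, marrow blood cell and cell division genes were called lower in the osteoarthritis libraries. Those of fibrous matrix and circadian clock genes were called higher. With an estimated correlation none was called (smallest adjusted p = 0.629), but that setting had little power with 2 samples against 2. Not all members agreed: 12 of 21 cartilage matrix genes lay below both controls and 10 of 22 fibrous matrix genes above both, and the fibrous matrix call was lost without osteoarthritis replicate 2. For single genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and the smallest adjusted p was 0.0824. At an unadjusted p under 0.05 the same test had 1858 genes higher and 1706 lower, where chance would give about 764 in all. DESeq2 called 1130 genes higher and 1266 lower, edgeR's likelihood ratio test 965 and 978, and limma-voom 0 and 0. Both DESeq2 and the likelihood ratio test called 847 of the higher and 972 of the lower genes. Without osteoarthritis replicate 1 the quasi-likelihood test called 1297 genes higher and 1105 lower, and without osteoarthritis replicate 2 it called 804 and 943; leaving out either control gave 0 and 0. The CPM of both osteoarthritis libraries lay above both controls for 4592 genes and below both for 4047, together 56.53% of the tested genes, where chance gives 33.3%. The median log2 fold change of all tested genes was 0.15, and it was 0.27 with library size alone as the scale and 0.05 with upper quartile factors. Fold changes below are osteoarthritis over control, and no named gene passed the quasi-likelihood test.

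Because no gene passed, the genes named first are those with the smallest unadjusted p in each direction, and all 16 had an adjusted p of 0.0824 in edgeR. Among those higher in osteoarthritis, Ccl21, a chemokine that attracts lymphocytes and dendritic cells, stood at 2.34 ± 0.169 CPM in control and 51.7 ± 7.77 CPM in osteoarthritis (SD, n = 2 each), a log2 fold change of 4.46 ± 0.38 (SE). Rodent genomes hold near-identical copies of this gene, so its count is uncertain. Cd34, a surface protein of blood vessel lining and of connective tissue progenitors, had 19.8 ± 1.05 and 131 ± 13.1 CPM, a log2 fold change of 2.72 ± 0.32. The other 6 were Zfhx3, a transcription factor, at 3.14, Arid5b at 3.24, Ankrd12 at 3.53, Filip1l at 3.12, Map1b, a microtubule-associated protein, at 3.54, and Cacna1c, a calcium channel subunit, at 2.73. Among those lower in osteoarthritis, Pla2g2a, a secreted phospholipase, had 158 ± 17.7 CPM in control and 4.76 ± 0.542 CPM in osteoarthritis, a log2 fold change of -5.06 ± 0.37. Ucma, a secreted protein of cartilage, had 190 ± 8.55 and 6.84 ± 2.52 CPM, a log2 fold change of -4.79 ± 0.44. PCOLCE2, an enhancer of procollagen processing, was at -4.23, Nrgn at -4.65 and Pttg1, the securin of dividing cells, at -3.80. Vpreb1 and Fcrla, both genes of B lineage cells, were at -6.04 and -4.66, and Jchain, which joins antibody subunits, was at -4.44. DESeq2 called all 16, with adjusted p from 6.93e-30 for Pla2g2a to 1.30e-07 for Cacna1c. The 16 were picked on the same counts, so this is no independent support. In the simulation of 15282 genes DESeq2 made 121 false calls at the estimated dispersions and 20 at a dispersion of 0.1. Whether false calls reach an adjusted p as small as those of the 16 was not examined.

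**Figure D2:**
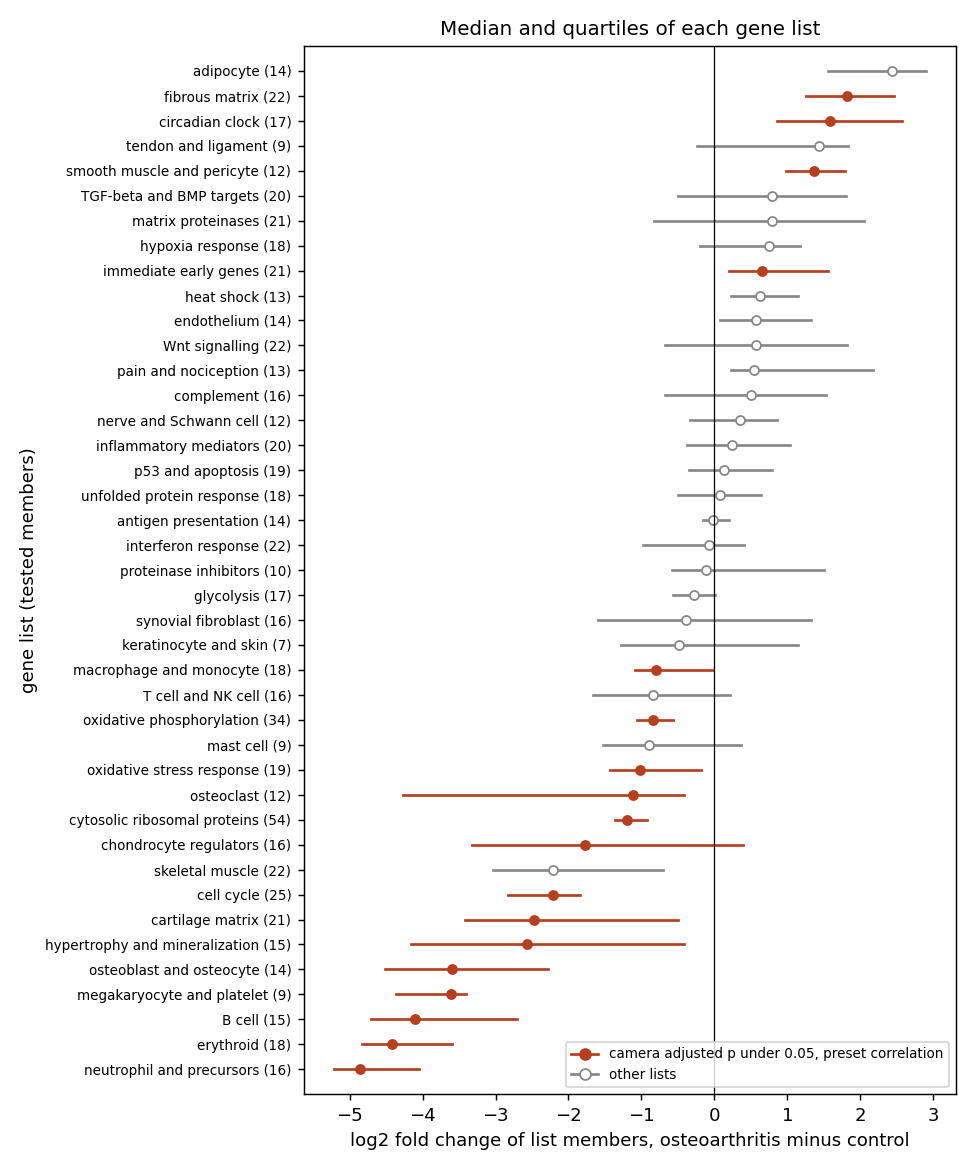
Median (point) and quartiles (line) of the log2 fold change, osteoarthritis minus control, over the tested members of each of the 41 gene lists, with the number of tested members in brackets. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, and the medians run from -4.86 for neutrophil genes to 2.43 for adipocyte genes, a list that was not called.

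Of the 41 gene lists, camera with a preset inter-gene correlation of 0.01 called 4 higher and 14 lower in osteoarthritis. With an estimated correlation it called 0, with a smallest adjusted p of 0.629, and fry, which asks whether the members of a list move on balance one way, also called 0, with a smallest adjusted p of 0.245. Fry's mixed test, which asks whether members move in either direction, called 2 lists that camera did not, mast cell (adjusted p = 0.00477) and p53 and apoptosis (0.0121). Every list call below is therefore a call at the preset correlation. The p-values of that setting compare the members of a list with the other genes. They do not measure the spread of a list between libraries. The estimated setting takes its degrees of freedom from 2 samples against 2, so it had little power to call any list. Its adjusted p does not show whether gene correlation overturns a call. The chondrocyte regulators and immediate early genes had estimated correlations of 0.00924 and -0.0107, below the preset 0.01, yet an adjusted p of 0.629. The other called lists had estimated correlations above the preset, from 0.0483 for oxidative stress response to 0.953 for megakaryocyte and platelet. Their p-values at the preset correlation may therefore be too small. The 18 calls with all libraries are given with their adjusted p at the estimated correlation, and those without 1 library at the preset correlation alone. No member of any list passed edgeR's quasi-likelihood test over all genes tested. DESeq2 called members of most lists, such as 21 of the cell cycle and 26 of the ribosomal protein list lower. It called 7 of the fibrous matrix and 10 of the circadian clock list higher. By edgeR, 142 list memberships passed when adjusted over the list alone. That criterion was not planned, is looser than the test over all genes and has no correction over the 41 lists.

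The cartilage matrix list was called lower in osteoarthritis at the preset correlation. Of 21 tested cartilage matrix genes, 17 had a negative log2 fold change and 12 lay below both controls, with a median of -2.48 (adjusted p = 2.33e-07 by limma's camera, adjusted p = 0.629 with an estimated correlation). Without control replicate 2 the median was -0.90 (adjusted p = 6.00e-05). Adjusted over the list alone, 6 were lower and 0 higher. Chad, chondroadherin, which anchors chondrocytes to collagen, had a log2 fold change of -4.69 ± 0.60, and Hapln1, the link protein of aggrecan, one of -2.69 ± 0.44. Col2a1, the main collagen of cartilage, had 13919 and 26813 CPM in the control libraries and 3430.7 and 385.16 CPM in the osteoarthritis libraries, a log2 fold change of -3.42 ± 1.25 (edgeR adjusted p = 0.194). Acan, the core protein of the main cartilage proteoglycan, went both ways, with 492.53 and 586.95 CPM in control and 70.855 and 2703.1 CPM in osteoarthritis (log2 fold change 1.36 ± 1.43). Without osteoarthritis replicate 2 its log2 fold change was -2.92. Sox9, the transcription factor that specifies chondrocytes, had 28.299 and 41.273 CPM in control and 19.537 and 189.01 CPM in osteoarthritis (1.58 ± 0.999, and -0.82 without osteoarthritis replicate 2). Markers of other tissues also differed between these 2 libraries: against the control mean, the median of the adipocyte list was 3.61 in osteoarthritis replicate 1 and -4.20 in replicate 2, and that of the tendon and ligament list -2.55 and 2.22. A difference in the dissected tissue is therefore not excluded as a source of the lower cartilage genes or of the split of Acan and Sox9.

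The 16 chondrocyte regulators had a median of -1.77 (camera adjusted p = 0.0167, adjusted p = 0.629 with an estimated correlation), with 6 lower and 1 higher, Erg at 1.45 ± 0.37, adjusted over the list alone. Erg is also a member of the endothelium list, so its level need not be that of chondrocytes. The call was lost without osteoarthritis replicate 1 (adjusted p = 0.372, median -1.45). Wif1, a secreted inhibitor of Wnt signalling, had a log2 fold change of -5.08 ± 0.92 and Fgfr3, a growth factor receptor that restrains cartilage growth, one of -2.02 ± 0.39. The 15 hypertrophy and mineralization genes had a median of -2.57 (camera adjusted p = 3.10e-06, adjusted p = 0.657 with an estimated correlation), with 9 lower and 0 higher adjusted over the list alone. Col10a1, the collagen of hypertrophic chondrocytes, had 59.626 and 290.91 CPM in control and 1.4585 and 0.25928 CPM in osteoarthritis (-7.64 ± 1.29, edgeR adjusted p = 0.0835). Phospho1, a phosphatase that starts mineral formation, was at -3.33 ± 0.44, and Mmp13, the main collagenase of cartilage, at -5.17 ± 1.59, with 61.597 and 282.01 CPM in control and 0.40702 and 9.1611 CPM in osteoarthritis.

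**Figure D3:**
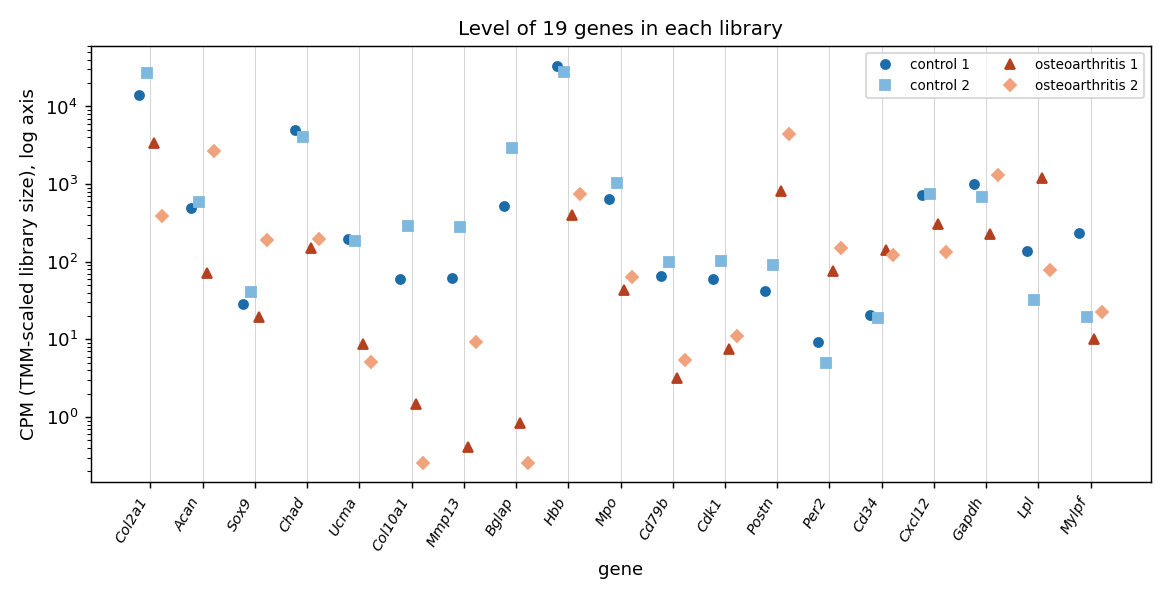
CPM on TMM-scaled library sizes, on a log axis, of cartilage, bone, blood cell, cell division, fibrous matrix, clock and other named genes, with 1 point per library. Col2a1, Chad and Ucma lie lower in both osteoarthritis libraries than in both controls, and Acan, Sox9 and Gapdh lie on either side of the controls.

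Both bone cell lists were called lower in osteoarthritis as well at the preset correlation. Below both controls lay 10 of 14 osteoblast and osteocyte markers and 7 of 12 osteoclast markers, and 2 osteoclast markers lay above both. The 14 osteoblast and osteocyte markers had a median of -3.60 (camera adjusted p = 3.36e-09, adjusted p = 0.657 with an estimated correlation), with 10 lower and 0 higher adjusted over the list alone. Bglap, osteocalcin, had 520.41 and 2913.9 CPM in control and 0.84795 and 0.25928 CPM in osteoarthritis, and Dmp1, an osteocyte matrix protein, had a log2 fold change of -4.63 ± 0.82. This list has 2 genes in common with the hypertrophy list, and its median log2 difference, control replicate 2 minus replicate 1, was 2.14. The 12 osteoclast markers had a median of -1.11 (camera adjusted p = 0.00283, adjusted p = 0.657 with an estimated correlation), with 4 lower adjusted over the list alone. That median moved with the libraries used, from -3.34 without osteoarthritis replicate 2 to -0.72 without control replicate 2. Acp5, the tartrate-resistant phosphatase of osteoclasts, was at -4.19 ± 1.03, and the other 3 were Car2 at -4.55, Mmp9 at -4.52 and Atp6v0d2 at -5.59. From osteoarthritis replicate 1 to 2, Car2 and Mmp9 rose from 9.02 to 66.9 and 3.80 to 25.3 CPM. Alas2 and Camp of the marrow lists rose alike, from 13.1 to 75.9 and 5.63 to 29.5 CPM. Mpo and Pf4 of those lists rose less, from 42.8 to 63.2 and 15.2 to 20.1 CPM. Acp5 also rose less (28.9 to 57.0 CPM) and Atp6v0d2 did not rise (0.271 to 0.130 CPM). A marrow source of Car2 and Mmp9 was not tested.

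Marrow blood cell lists had low medians, like the osteoblast list, and their order changed with the libraries used. The median log2 fold change was -4.86 for 16 neutrophil and precursor genes (camera adjusted p = 1.44e-18), -4.42 for 18 erythroid genes (7.62e-20), -4.11 for 15 B cell genes (5.57e-19) and -3.60 for 9 megakaryocyte and platelet genes (7.73e-11). Each of these 4 lists had an adjusted p = 0.629 with an estimated correlation. The osteoarthritis libraries differed in how low they were: the median log2 difference, replicate 2 minus replicate 1, was 3.13 for the neutrophil, 2.87 for the erythroid, 2.997 for the megakaryocyte and 0.28 for the B cell list. Without osteoarthritis replicate 2 the 4 medians were -7.00 (neutrophil), -6.21 (erythroid), -4.37 (B cell) and -6.14 (megakaryocyte). Adjusted over the list alone, 16, 15, 12 and 8 of their members were lower, and 1 gene of the B cell list was higher, Ebf1 at 2.03 ± 0.56, a transcription factor also used by fat and stromal cells, named after its value was seen. Mpo, the myeloperoxidase of neutrophils, had a log2 fold change of -3.97 ± 0.52, Camp, an antimicrobial peptide, -5.38 ± 0.96, Cd79b, part of the B cell receptor, -4.26 ± 0.48, Alas2, the first enzyme of heme synthesis in red cells, -4.48 ± 0.96, and Pf4, platelet factor 4, -3.60 ± 0.36. Hbb, beta globin, had 33429 and 27491 CPM in control and 404.57 and 742.83 CPM in osteoarthritis. Globin genes, whose near-identical copies can share reads, took 12.0% and 12.37% of the control counts and 0.217% and 0.552% of the osteoarthritis counts. The 18 macrophage and monocyte genes had a median of -0.80 (camera adjusted p = 0.00448, adjusted p = 0.657 with an estimated correlation). Of these, 14 had a negative and 4 a positive log2 fold change, and 11 lay below both controls and 2 above both. Adjusted over the list alone, 4 were lower, Lyz2, lysozyme, at -2.97 ± 0.77, Tyrobp at -2.68, Fcer1g at -1.96 and Cd68 at -1.43. The median of that list was -1.73 without osteoarthritis replicate 1 and -0.41 (adjusted p = 0.0469) without osteoarthritis replicate 2.

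All 25 cell cycle genes were lower in both osteoarthritis libraries than in both controls, with a median of -2.22 (camera adjusted p = 1.11e-21, adjusted p = 0.629 with an estimated correlation), and 25 were lower adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, was at -3.12 ± 0.45 and Plk1, a mitotic kinase, at -3.37 ± 0.49. The marrow lists and the globin share above were lower in the same libraries.

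The fibrous matrix list was called higher at the preset correlation, and most of the difference lay in osteoarthritis replicate 2. Of 22 genes, 10 lay above both controls and 21 had a positive log2 fold change, with a median of 1.81 (camera adjusted p = 0.000821, adjusted p = 0.909 with an estimated correlation), and 0 passed adjusted over the list alone. Against the control mean, the list's median was 0.33 in osteoarthritis replicate 1 and 2.74 in osteoarthritis replicate 2, and without replicate 2 the call was lost (adjusted p = 0.501, median 0.20). Tendon and ligament markers were higher in the same library, with a median against the control mean of -2.55 in replicate 1 and 2.22 in replicate 2, so tissue of that kind in replicate 2 is not excluded. Postn, periostin, a protein of remodelling connective tissue, had 41.851 and 91.714 CPM in control and 822.65 and 4448.9 CPM in osteoarthritis (5.30 ± 1.09). Col6a3, a chain of collagen VI, was at 2.59 ± 0.85 and Fbn1, fibrillin, at 2.23 ± 0.66. The 12 smooth muscle and pericyte markers had a median of 1.37 (camera adjusted p = 0.00292, adjusted p = 0.657 with an estimated correlation), with 0 passing adjusted over the list alone. That call was lost without control replicate 2 (adjusted p = 0.166, median 0.97). Notch3, a receptor of vessel wall cells, had a log2 fold change of 1.32 ± 0.38 and Abcc9, a channel regulator of pericytes, one of 1.87 ± 0.40.

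Of 17 circadian clock genes, 15 had a positive log2 fold change, with a median of 1.59 (camera adjusted p = 8.63e-06, adjusted p = 0.657 with an estimated correlation), and 9 were higher and 0 lower adjusted over the list alone. Per2 and Per3, period genes that repress the clock's activators, were at 4.01 ± 0.56 and 2.62 ± 0.35, and Hlf, a clock-controlled transcription factor, was at 3.97 ± 0.63. No time of day is given in the labels used here. The 21 immediate early genes, which respond within minutes to stimuli and to tissue handling, had a median of 0.65 (camera adjusted p = 0.0272, adjusted p = 0.629 with an estimated correlation), with 0 passing adjusted over the list alone. Without control replicate 1 that call was lost (adjusted p = 0.113, median 1.03). Fos and Jun, the components of the AP-1 transcription factor, were at 1.91 ± 0.36 and 1.46 ± 0.36.

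The lists of ribosomal protein, oxidative phosphorylation and oxidative stress genes were called lower, and these calls ended when a trend with gene length was removed. All 54 cytosolic ribosomal protein genes had a negative log2 fold change, with a median of -1.19 (camera adjusted p = 2.98e-11, adjusted p = 0.692 with an estimated correlation), and 0 passed adjusted over the list alone. Rps14 was at -2.01 ± 0.51 and Rpl37 at -1.45 ± 0.35, and both, like other ribosomal protein genes, have processed pseudogenes that can share their reads. The 34 oxidative phosphorylation genes had a median of -0.84 (camera adjusted p = 4.92e-06, adjusted p = 0.736 with an estimated correlation), with 0 passing adjusted over the list alone, and Cox5a, a subunit of cytochrome oxidase, was at -1.92 ± 0.39. The 19 oxidative stress genes had a median of -1.02 (camera adjusted p = 0.000546, adjusted p = 0.629 with an estimated correlation), with 3 lower adjusted over the list alone. Sod1, superoxide dismutase, was at -1.46 ± 0.35, Gpx1, glutathione peroxidase, at -2.87 ± 0.50 and Gclm, a subunit of the enzyme that limits glutathione synthesis, at -2.31 ± 0.37. The log2 fold change of all tested genes increased with gene length, from a median of -0.65 in the shortest quintile to 0.81 in the longest. The ribosomal, oxidative phosphorylation and oxidative stress genes had median lengths of 699, 1038 and 1488 bases, and the clock and fibrous matrix genes of 3959 and 4614 bases. With the length trend removed in each library, a setting chosen after seeing the data, the first 3 lists were no longer called (adjusted p = 0.819, 0.866 and 0.0991), the other 15 calls held, with the fibrous matrix median going from 1.40 ± 0.32 to 0.93 ± 0.32 (SE) and that of the clock from 1.67 ± 0.52 to 1.17 ± 0.53, and heat shock was called higher (adjusted p = 0.0289, 0.778 with an estimated correlation). The 3 calls ended because the medians of log2 CPM differences moved towards 0, from -1.20 ± 0.06 to -0.02 ± 0.07, -0.86 ± 0.11 to 0.01 ± 0.10 and -1.04 ± 0.27 to -0.24 ± 0.26. These standard errors of medians come from the spread over list members taken as independent. They leave out the spread between libraries and are likely too small.

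**Figure D4:**
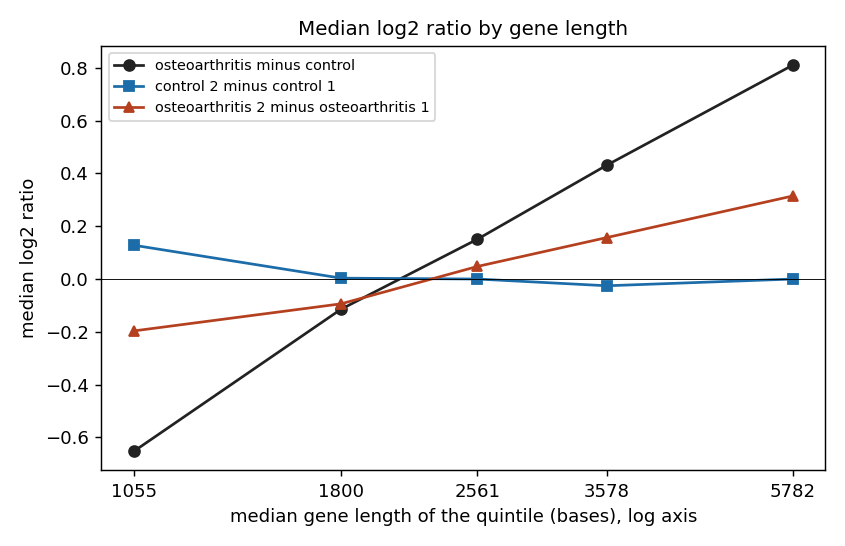
Median log2 ratio of quintiles of the tested genes ordered by gene length, against the median length of each quintile in bases on a log axis, for osteoarthritis minus control and for the difference between the libraries of each group. The ratio between groups runs from -0.65 at 1055 bases to 0.81 at 5782 bases, the one between the osteoarthritis libraries from -0.20 to 0.31, and the control libraries differ by at most 0.13.

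The lists for inflammation, pain and glycolysis were not called. The 20 tested inflammatory mediators had a median of 0.24 (camera adjusted p = 0.812). Il1b, interleukin 1 beta, had 5.90 ± 0.229 CPM in control and 4.57 ± 3.23 CPM in osteoarthritis, a log2 fold change of -0.37 ± 0.80. Cxcl12, a chemokine of stromal cells, had 738 ± 9.94 and 220 ± 121 CPM (-1.75 ± 0.54, edgeR adjusted p = 0.156). Ptgs2, cyclooxygenase 2, had 0 and 0.23015 CPM in control and 0.81403 and 13.396 CPM in osteoarthritis (5.91 ± 2.17, edgeR adjusted p = 0.194), and Il6, with 58 and 8 counts in control and 7 and 8 in osteoarthritis, was below the expression filter. The 13 pain genes had a median of 0.55 (camera adjusted p = 0.292). Without control replicate 2 that list was called higher (adjusted p = 0.0195, median 3.03). Bdkrb2, a bradykinin receptor, was at 2.17 ± 0.56, and Cxcr4, the receptor of Cxcl12, at -2.15 ± 0.59. The 17 glycolysis genes had a median of -0.28 (camera adjusted p = 0.394). Gapdh, a glycolytic enzyme often used as a reference gene, had 990.83 and 683.73 CPM in control and 229.32 and 1324.9 CPM in osteoarthritis, and Hk2, hexokinase 2, was at 2.00 ± 0.40. Without osteoarthritis replicate 2 the glycolysis list was called lower (adjusted p = 1.42e-05, median -1.15).

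Matrix proteinases and their inhibitors were not called either. The 21 proteinases had a median of 0.79 (camera adjusted p = 0.610), and without osteoarthritis replicate 1 they were called higher (adjusted p = 0.0294, median 0.73). Mmp3, stromelysin 1, had a log2 fold change of -2.33 ± 0.90 (-4.16 without osteoarthritis replicate 2 and -1.56 without replicate 1), Adamts5, an aggrecanase, one of 0.85 ± 0.53, and Adamts1, a related proteinase, one of 3.60 ± 0.85. The 10 inhibitors had a median of -0.12 and a mean of 0.58 (camera adjusted p = 0.829, with the test leaning lower). Timp1, a metalloproteinase inhibitor, had 125 ± 2.92 and 116 ± 83.6 CPM.

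Of the other programme lists, none was called with all libraries. The camera adjusted p was 0.314 for hypoxia response (median 0.75), 0.273 for heat shock (0.63), 0.292 for TGF-beta and BMP targets (0.79), 0.812 for Wnt signalling (0.57), 0.163 for interferon response (-0.07) and 0.193 for antigen presentation (-0.02). For p53 and apoptosis it was 0.911 (median 0.13, mean 0.21), for unfolded protein response 0.845 (median 0.08, mean -0.02) and for complement 0.812 (median 0.50, mean 0.37), and in these 3 lists the test leaned lower. Without osteoarthritis replicate 1, hypoxia response and heat shock were called higher (adjusted p = 0.00778 and 0.0189), and interferon response and antigen presentation lower (adjusted p = 0.000611 and 3.39e-07). Interferon response was also called lower without control replicate 2 (adjusted p = 0.000916). Within that list Rsad2 and Ifit1, antiviral effectors, were at -3.80 ± 0.67 and -5.57 ± 1.04, and both were lower adjusted over the list alone. The other members to pass adjusted over the list alone were Ltbp1 of the TGF-beta list, higher at 1.78 ± 0.31, and of complement C7, higher at 1.58 ± 0.32, and C5ar1, lower at -2.63 ± 0.45. The inflammation, pain, glycolysis, proteinase, inhibitor and remaining programme lists that were not called had 0.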

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

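The alternatives were fixed before the data were examined, except 5 added after: a filter at a mean of 200 counts, bias-adjusted deviances in edgeR, upper quartile factors for the lists, and camera on log2 CPM with and without a length trend removed. The counts of genes higher and lower, 0 and 0 in edgeR's quasi-likelihood test, were 0 and 0 with the other scalings, limma-voom, the CPM filter, the filter at 200 counts, a fold threshold, bias-adjusted deviances, without the 10 genes with the most counts, and in limma-trend on log2(FPKM + 1) without a filter. They were 1130 and 1266 with DESeq2, 965 and 978 with the likelihood ratio test and 677 and 751 without a filter beyond 1 read. Limma-trend on genes with a mean FPKM of at least 0.5 gave 58 and 271 with a pseudocount of 1, and 19 and 116 with 0.1. Leaving out 1 library gave 0 to 1297 higher and 0 to 1105 lower genes. The prior degrees of freedom were 3.34 with all libraries, 13.2 without a filter, and 12.5 and 19.3 without osteoarthritis replicate 1 and 2. The cause of the moves was not tested. Of the 41 lists, 18 were called, and 0 with an estimated correlation or fry. Every further alternative used camera at the preset correlation on these libraries, so calls kept there do not test that correlation. The other alternatives, including the fits that leave out 1 library, called 16 to 26, and each kept at least 15 of the 18 in the same direction. Skeletal muscle was called lower with library size only (adjusted p = 0.0208) and the filter at 200 counts (0.0492), and T cell and NK cell with library size only (0.0434) and the CPM filter (0.0334). Over the fits that leave out 1 library, list medians ran from -2.86 to -0.90 for cartilage matrix, -4.59 to -2.32 for osteoblast and osteocyte, -3.34 to -0.72 for osteoclast, -1.73 to -0.41 for macrophage and monocyte, -7.00 to -4.05 for neutrophil, -6.21 to -3.73 for erythroid, -6.14 to -2.90 for megakaryocyte, -0.93 to -0.65 for oxidative stress response, 1.04 to 1.96 for circadian clock and 0.84 to 1.97 for smooth muscle and pericyte. Pearson's r of the control pair was 0.861, and 0.946 on log2(FPKM + 1). That of the osteoarthritis pair was 0.869, 0.887 on log2(FPKM + 1) and 0.844 with the CPM filter.

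Of 1304 values of 87 named genes under the alternatives, 859 kept direction and side of the threshold, 431 passed the threshold in the same direction, and 14 changed sign. Acan was at -0.25 in limma-voom, -0.16 on log2(FPKM + 1) with and without the filter, and -0.19 on log2(FPKM + 0.1). Over the fits that leave out 1 library, log2 fold changes ran from -2.92 to 2.29 for Acan, -0.82 to 2.40 for Sox9, -1.14 to 0.45 for Timp1, -1.40 to 0.23 for Il1b, -1.86 to 0.64 for Gapdh, -0.13 to 4.26 for Lpl, -1.26 to 13.39 for Lep, -0.87 to 4.37 for Pparg and -2.55 to 3.37 for Thbs4. Without a change of sign they ran from -5.77 to -2.56 for Col2a1, -8.69 to -3.68 for Mmp13, -4.16 to -1.56 for Mmp3, 0.43 to 1.36 for Adamts5, 2.30 to 4.33 for Adamts1, 2.79 to 10.59 for Ptgs2, -5.05 to -2.29 for Acp5, -6.47 to -3.37 for Atp6v0d2, 1.20 to 2.79 for Fbn1, 1.23 to 3.23 for Col6a3, 1.39 to 5.36 for Tnmd, -3.84 to -0.30 for Mylpf, -4.43 to -1.72 for Tnni2 and 1.21 to 2.56 for Ebf1. The 13.39 of Lep and 10.59 of Ptgs2 are fitted against a control at 0 and are no bounds. The lowest was without osteoarthritis replicate 2 for Acan, Sox9, Timp1, Gapdh and Thbs4 and without osteoarthritis replicate 1 for Il1b, Lpl, Lep and Pparg. No paired analysis was possible because the labels give no replicate numbers that link samples across groups. Depth limits genes such as Il6 that have under 10 counts in some libraries.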

Other observations

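The tests of the marrow and low count patterns below, and the test of length as the whole source of the clock list, were chosen after their results were seen, and the other tests of the length pattern before. The libraries of 1 group differed from each other in the genes of neighbouring tissues. The median log2 difference of 14 adipocyte genes, osteoarthritis replicate 2 minus replicate 1, was -7.57. Lpl, lipoprotein lipase, had 1201.8 CPM in replicate 1 and 78.431 CPM in replicate 2, Pparg, the regulator of fat cell formation, 166.74 and 6.1794 CPM, and Lep, leptin, 98.871 and 0.25928 CPM. The list was not called with all libraries (median 2.43, camera adjusted p = 0.576), was called higher without osteoarthritis replicate 2 (adjusted p = 3.66e-07) and lower without osteoarthritis replicate 1 (8.45e-06). Nerve and Schwann cell genes followed the same library, with a median difference of -4.16, and that list (median 0.35, mean 0.29, test leaning lower, adjusted p = 0.687) was called in opposite directions without either osteoarthritis library (0.00645 without replicate 2, 0.000356 without replicate 1). Tendon and ligament genes went the other way, 3.61 higher in osteoarthritis replicate 2. Thbs4, a thrombospondin of tendon, had 59.696 and 3718.9 CPM and Tnmd, tenomodulin, 23.573 and 380.58 CPM. That list was not called with all libraries (median 1.43, adjusted p = 0.812), and was called higher without replicate 1 (0.00344) and lower without replicate 2 (0.0301).

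The median log2 difference of 22 skeletal muscle genes, control replicate 2 minus replicate 1, was -3.96. Mylpf and Tnni2, proteins of fast muscle fibres, had 235.62 and 154.52 CPM in control replicate 1 and 19.294 and 22.439 CPM in control replicate 2. The list had a median of -2.22 (camera adjusted p = 0.0544), was called higher without control replicate 1 (adjusted p = 0.0265) and lower without control replicate 2 (1.08e-13) or osteoarthritis replicate 2 (0.0268). Other cell type lists that were not called were T cell and NK cell (median -0.84, adjusted p = 0.0544, called lower without control replicate 2 at 0.0229 and without osteoarthritis replicate 1 at 0.0079), endothelium (0.57, 0.132, called higher without control replicate 1 at 0.00723 and without osteoarthritis replicate 2 at 0.0111), mast cell (-0.90, 0.249, and 0.00477 in fry's mixed test), synovial fibroblast (-0.38, 0.766) and keratinocyte and skin (-0.49, 0.812). Adjusted over the list alone, Nkg7 of the T cell and NK cell list was lower (-4.55 ± 0.53, SE), and in the synovial fibroblast list 4 genes were higher and 3 lower, with Cd34 at 2.72 and Prg4, lubricin, at -4.65. The other lists of this part had 0. The 3 splits of the 4 libraries are too few for a share under 0.05. The real one had 3564 genes at an unadjusted p under 0.05 by edgeR and the highest other 294, and each had 0 genes at an adjusted p under 0.05.

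Most marrow-cell genes were lower in both osteoarthritis libraries than in both controls. These were 16 of 16 neutrophil, 17 of 18 erythroid, 14 of 15 B cell and 9 of 9 megakaryocyte genes. The other B cell gene, Ebf1, lay above both controls. Less marrow in the dissected osteoarthritis tissue stays open. The medians of the erythroid, neutrophil, B cell and megakaryocyte lists lay within 1.26 of each other with both osteoarthritis libraries and within 1.11 in replicate 2, as one loss of marrow would give, but they spanned 2.64 in replicate 1, where B cell genes fell less than the others. Of the bone markers, 10 of 14 osteoblast and 7 of 12 osteoclast genes lay below both controls in the same libraries, and 2 osteoclast genes above both. A difference in the tissue due to disease or treatment stays open and was not tested apart from dissection.

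The control libraries held few genes at low counts. Lower depth is argued against as the whole source, also if control fragments were counted as 2 reads: genes with 1 to 10 counts made up 3.34% and 6.60% of those detected in control, and the higher share is 0.396 of the lower share with 1 to 5 counts expected in osteoarthritis at 0.5 of its depth (16.8% and 16.7%). Genes with 1 to 5 counts made up 2.15% and 3.21% of the detected genes in control and 13.4% and 15.5% in osteoarthritis, and among genes with 21 to 50 counts the even counts were 70.5% (95% exact binomial interval 67.6 to 73.2) and 66.4% (63.8 to 68.9) in control against 48.5% (45.9 to 51.0) and 48.4% (45.5 to 51.4) in osteoarthritis. Among genes with 200 to 1000 counts the even counts were 50.6% in each control library, and 50.4% and 49.2% in osteoarthritis. Counting each fragment as 2 reads is argued against as the whole source. The control share of detected genes with 1 or 2 counts was 0.339 of the osteoarthritis share with 1 count. The even counts among genes with 21 to 50 counts leave it open in part. Few molecules amplified into many reads may account for the pattern: genes with at least 50 counts in 1 library and 0 in the other were 9.16 times as many in the control pair as in the osteoarthritis pair (458 against 50). Differences in tissue between the control libraries, which their muscle genes show, may add to that ratio and were not removed. The counting intervals of low genes are too narrow if reads are not independent.

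Longer genes were higher in the osteoarthritis libraries, with a slope of 0.54 in log2 fold change per doubling of length. A trend that varies between single libraries is argued against, because the larger slope within a pair of libraries was 0.274 of that between groups, so the trend follows the groups and cannot be separated from them. With the trend over all genes removed from the fold changes, the median of the ribosomal protein list was -0.0869, against -1.19 before, so the trend may account for that list. The median of the clock list was 0.985, with a standard error of 0.50, against 1.59 before, so the test chosen before leaves open how much of it length accounts for, and the 2 cannot be told apart at that spread. Length as the whole source of the clock list is argued against at the preset correlation only. With the trend removed in each library the list was still called higher there (camera adjusted p = 0.000661, 0.726 at the estimated one). Its median was 1.17 ± 0.53 (SE) against 1.67 ± 0.52 before. That SE takes list members as independent and leaves out the spread between libraries, while the estimated correlation of the list was 0.532. At the estimated correlation the list was not called before or after. RNA quality, library preparation and biology could each give such a trend, and the labels give nothing to part them.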
